A study of Homo sapiens with 8 samples.

How the data were processed

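Chromatin accessibility was measured in human CD8 T cells that had been sorted by flow cytometry on the surface protein CD38 and frozen. CD38 is an enzyme that consumes NAD and is raised on activated T cells. Libraries were made with omniATAC, a form of ATAC-seq in which the transposase Tn5 inserts sequencing adapters into open chromatin, so that stretches with many fragment ends are read as accessible. The labels name 8 libraries in 4 groups of 2, a CD38high and a CD38low library from each of 2 healthy donors (HC) and 2 donors labelled SLE, the usual abbreviation of systemic lupus erythematosus. The design text of the series speaks of biological duplicates.

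The deposited files are peak lists, 1 per library. Per the submitters' processing notes, the tools were Bowtie2, MACS2, FastQC and DiffBind and the build was hg19, with versions and settings not given in the sources used here. Per the peak names in the deposited files, MACS2 was run on each library separately and on nucleosome-free fragments, so replicates were not pooled. Each peak has a start, an end and the authors' whole-number score. The lowest score is 13 in every library, the value that MACS2 gives to a q of 0.05. The score rises with read depth and was used only to rank peaks within a library. Whether fragment ends were shifted for the way Tn5 binds, and how duplicates and mitochondrial reads were treated, is not given in the sources used here. No read number is given, so the depth of each library is unknown. A deeper library yields more and weaker peaks, and the number of peaks therefore mixes accessibility with depth and signal over background. No interval from read counts could be computed.

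The 22 autosomes alone entered every comparison, which kept 96.5% to 97.3% of the peaks of each library. No filter for repeats or other stretches prone to mapping artifacts was applied here. Peaks of the 8 libraries were merged where they overlapped by 1 bp or more. This gave 162416 regions, of which the 74172 called by at least 2 libraries were kept as consensus regions. A library calls a region where at least 1 of its peaks overlaps it by 1 bp. A region counts as called in a single arm where all libraries of that arm and none of the other call it. The count expected without any tie between libraries was computed from each library's odds of calling a region, among regions called by as many libraries. Because libraries differ in peak number, each such count was also made with the 28206 best-scoring autosomal peaks of every library, the number in the smallest library. These are called equal peak numbers.

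Comparisons were CD38high against CD38low in HC donors, in SLE donors and in the 4 donors together, and SLE against HC in each sort and over both. Numbers of peaks, covered length and width were compared by exact permutation over the 70 assignments of 4 libraries against 4, 2-sided. A group of 2 libraries against 2 cannot give an exact p below 0.33. SLE against HC over both sorts has 4 libraries in each arm from only 2 donors, so these libraries are not independent. Overlaps of region lists were set beside the overlap of independent lists of the same sizes, with exact 95% Poisson intervals. Regions are not replicates, and these intervals cover counting error only. Independent lists were taken from all consensus regions, including those called by every library, which can enter no list. Ratios above 1 are therefore partly built in. The ratio of same to opposite directions does not depend on this.

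The plan fixed before the data were examined was a limma fit of accessible length per gene, with gene lists, promoter shares and sequence motifs. It needs a gene annotation or a sequence of hg19, and none was used here: the gene table at hand is on GRCh38, and coordinates were not converted between builds. As a check of the builds, 4.02% of 19126 protein-coding genes of that table had one of the 20000 strongest peaks of the HC donor 2 CD38low library within 500 bp of an end. With the positions shifted by 1 or 2 Mb this share was 1.95% to 2.48%. The table was used for nothing else, and no gene names are assigned to regions. The plan's rule for this case names the 5 longest regions called in a single arm per direction and comparison, by coordinates. Its rule for genes past the limma threshold, up to 10 per direction by largest fold, was applied to the bins past the threshold at equal peak numbers, as none passed with all peaks.

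In place of genes, covered length was summed in bins of 100 kb, a choice made after the files were seen. limma 3.58.1 in R 4.3.3 was fitted to log2(covered bp + 100), quantile normalized, in bins with a mean covered length of at least 200 bp, with 4 group means over the 8 libraries and Benjamini-Hochberg adjustment at 0.05. Of 25135 bins with a peak, 10545 were tested, and 8318 at equal peak numbers. Fold changes on this scale understate the change of bins with little covered length. In simulated data with the spread of these bins, for CD38high against CD38low over 10545 bins, 33% of bins with a planted log2 change of 1 and 99% of those with a planted change of 3 were recovered, with 12 false calls. The count of regions called in a single sort recovered 200 of 200 planted regions among 60000 simulated ones. As planted regions met the counting rule by definition, this checks the counting only and says nothing about sensitivity.

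The donor numbers in the titles pair the CD38high and CD38low library of a donor. Deviations of the libraries from their group means correlated across bins between the libraries of a donor with r = 0.43 in HC and 0.14 in SLE, over bins, which are not independent. Fits with the donor as a block are given for the sorts in bins, and elsewhere where they change a count of calls. Alternatives covered stricter and equal numbers of peaks, other overlap rules, other bins, scalings and pseudocounts, and leaving out each library. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.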

Results

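ATAC-seq peaks were compared between CD8 T cells with high and low surface CD38 from 2 HC and 2 SLE donors, 8 libraries in all. The libraries held between 29102 peaks, in SLE donor 2 CD38low, and 97555, in SLE donor 2 CD38high. On autosomes the peaks covered 4.14 Mb in HC donor 1 CD38high and 16.8 Mb in SLE donor 2 CD38high. Peaks were narrowest in HC donor 1, with a median width of 72 bp in CD38high and 73 bp in CD38low cells. The other 6 libraries had medians of 115 bp to 146 bp. Peaks found in no other library made up 5.57% to 9.78% of 5 libraries, but 27.8% and 35.8% of the HC donor 1 CD38high and CD38low libraries and 31.1% of SLE donor 2 CD38high. The read depth behind these numbers is unknown.

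**Figure D1:**
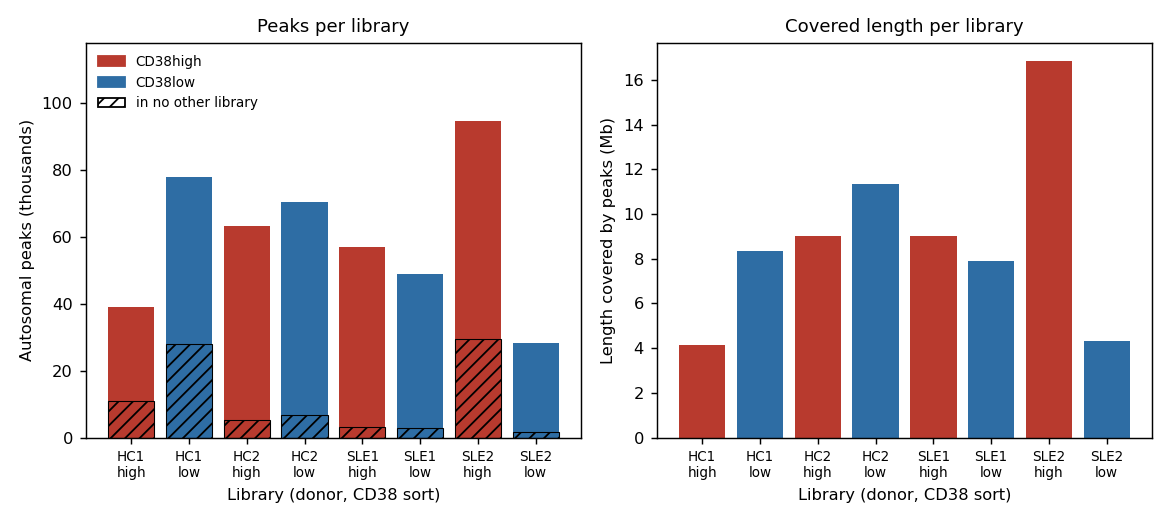
Autosomal peaks (left, in units of 1000) and the length they cover (right, Mb) in each of the 8 libraries, named by donor and CD38 sort, with hatching for peaks that no other library overlaps. Autosomal peaks range from 28206 to 94599, and the CD38high library has fewer than the CD38low library in both HC donors and more in both SLE donors.

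A shared core of open chromatin was found in every library. Of the 74172 consensus regions, 17039 (23.0%) were called by all 8 libraries. With equal peak numbers 12769 of 36345 regions (35.1%) were called by all 8. A further 88244 merged regions were called by a single library and are not among the consensus regions. The Jaccard index of covered bases ran from 0.193 to 0.599 over the 28 pairs of libraries. The mean index at equal peak numbers was 0.530 for the CD38high and CD38low libraries of the same donor (4 pairs). It was also 0.530 for libraries of the same sort and disease group from different donors (4 pairs), 0.492 for libraries of the same sort from the other disease group (8 pairs), 0.491 for those of the other sort from the other disease group (8 pairs) and 0.486 for those of the other sort and another donor of the same group (4 pairs). With all peaks these 5 means were 0.438, 0.425, 0.404, 0.433 and 0.386. Pairs share libraries, so these means were not tested.

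**Figure D2:**
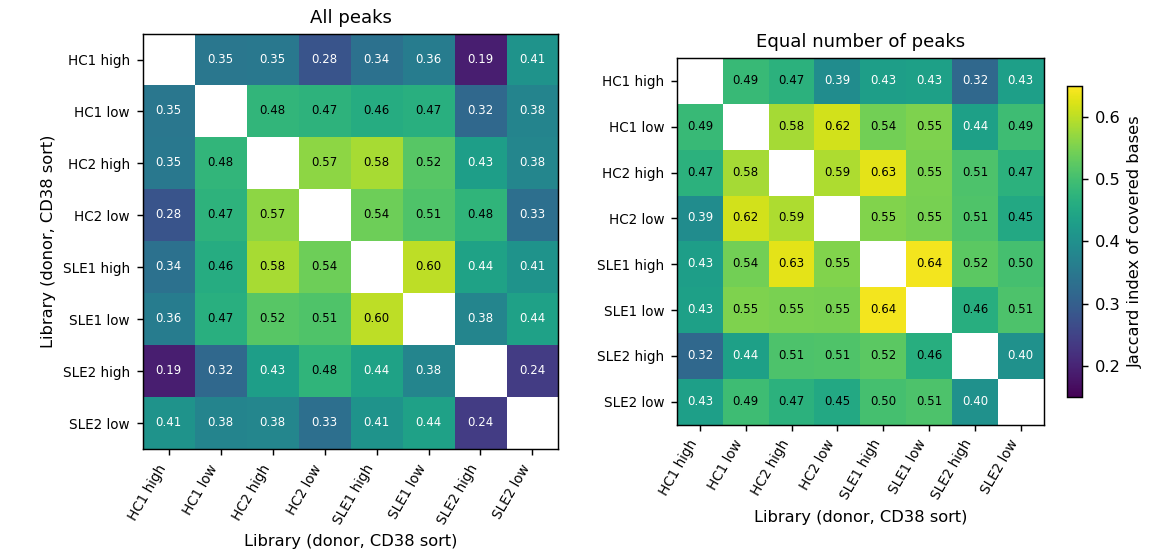
Jaccard index of covered bases for each pair of the 8 libraries, with all peaks (left) and with the 28206 best-scoring peaks of each library (right), rows and columns being donor and CD38 sort. The lowest index with all peaks is 0.193, between HC donor 1 CD38high and SLE donor 2 CD38high, and the highest at equal peak numbers is 0.641, between the libraries of SLE donor 1.

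The series title sets CD38low against CD38high cells, and the first comparison asks how open chromatin differed between them. CD38high libraries held 63390 ± 23179 autosomal peaks and CD38low libraries 56346 ± 22462 (SD, n = 4 each, exact permutation p = 0.686). Covered length was 9.75 ± 5.25 Mb and 7.97 ± 2.87 Mb (SD, n = 4 each, exact permutation p = 0.571), and neither difference was larger than the spread between libraries. The difference in peak number turned direction without SLE donor 2 CD38high (-3360 peaks, and -0.585 Mb of covered length) or SLE donor 2 CD38low (-2337 peaks). Median peak width, 115 bp against 117 bp, did not differ either (exact permutation p = 0.914).

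Over the 4 donors, 89 regions were open in every CD38high library and no CD38low library, and 20 in every CD38low and no CD38high library. From the libraries' odds of calling a region 42.0 and 8.37 were expected, so the counts lay 2.12 and 2.39 times above that. The counts were 77 and 96 at equal peak numbers, 2.42 and 1.54 times the expected 31.9 and 62.5. The split between directions thus moved from 81.7% to 44.5% in CD38high when peak numbers were made equal. With all peaks the counts were 93 and 263, the other way round, without SLE donor 2 CD38low, and 1251 and 22 without HC donor 1 CD38high. No single region passes a test with 4 donors, since an exact sign test cannot go below 0.125.

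The 5 longest regions open in CD38high cells alone over the 4 donors lie on hg19 chromosome 19 at 11679042 to 11679460 (419 bp), chromosome 2 at 234262817 to 234263222 (406 bp), chromosome 4 at 125633833 to 125634234 (402 bp), chromosome 9 at 101998173 to 101998560 (388 bp) and chromosome 5 at 172276749 to 172277122 (374 bp). The region on chromosome 19 had authors' scores between 35 and 1463 in the 4 CD38high libraries. It reached the percentiles 35.1 to 94.7 of the scores within those libraries. Median width was 170 bp over the 89 regions open in CD38high alone and 149 bp over the 20 open in CD38low alone. The 5 longest open in CD38low cells alone, taken from the shorter list, were shorter, from 200 bp to 259 bp. They lie on chromosome 18 at 75333996 to 75334254, chromosome 11 at 67060679 to 67060911, chromosome 5 at 74324002 to 74324219, chromosome 10 at 121415284 to 121415500 and chromosome 2 at 65593793 to 65593992. None of these 10 regions met the rule at equal peak numbers. There every list but that of SLE donor 2 CD38low holds only its strongest entries.

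Within HC donors 389 regions were open in CD38high cells alone and 4494 in CD38low cells alone. The HC direction turned without HC donor 1 CD38high, to 5186 and 4913, an arm of 1 library admitting more regions by construction. Within SLE donors the counts were 9230 and 84, and no single library turned that direction. In both disease groups the larger count lay in the sort whose libraries held more peaks. The expected counts were 277 and 4382 in HC, and 9257 and 111 in SLE. The odds behind them were fitted to the same regions, which fixes the difference between the 2 directions. The expected counts therefore say nothing about the source of that difference. The counts at equal peak numbers were 1381 and 2265 in HC and 1039 and 936 in SLE, so that the share open in CD38high alone was 37.9% in HC and 52.6% in SLE instead of 7.97% and 99.1%. In HC donors the 3646 regions that parted the sorts at equal peak numbers were 1.58 times the expected number, above the split of the same libraries by donor (0.997) and the crossed split (0.379). With all peaks the order was the other way, 1.05 for the split by sort and 1.11 for the split by donor. In SLE donors the split by sort gave 0.926 times the expected number and the split by donor 1.52, and 0.994 and 1.21 with all peaks. Over the splits of the same libraries, observed and expected counts have the same total. A deficit in one split thus appears as an excess in another, and these ratios are not independent. The longest regions open in CD38high HC cells alone lie on chromosome 22 at 35695448 to 35695944 (497 bp) and chromosome 1 at 954749 to 955228 (480 bp), and all 5 named regions of this direction met the rule at equal peak numbers too. The longest in CD38low HC cells lies on chromosome 13 at 100009108 to 100009819 (712 bp). In SLE donors the longest lie on chromosome 12 at 107856215 to 107857179 (965 bp) for CD38high and on chromosome 20 at 47131709 to 47132241 (533 bp) for CD38low.

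**Figure D3:**
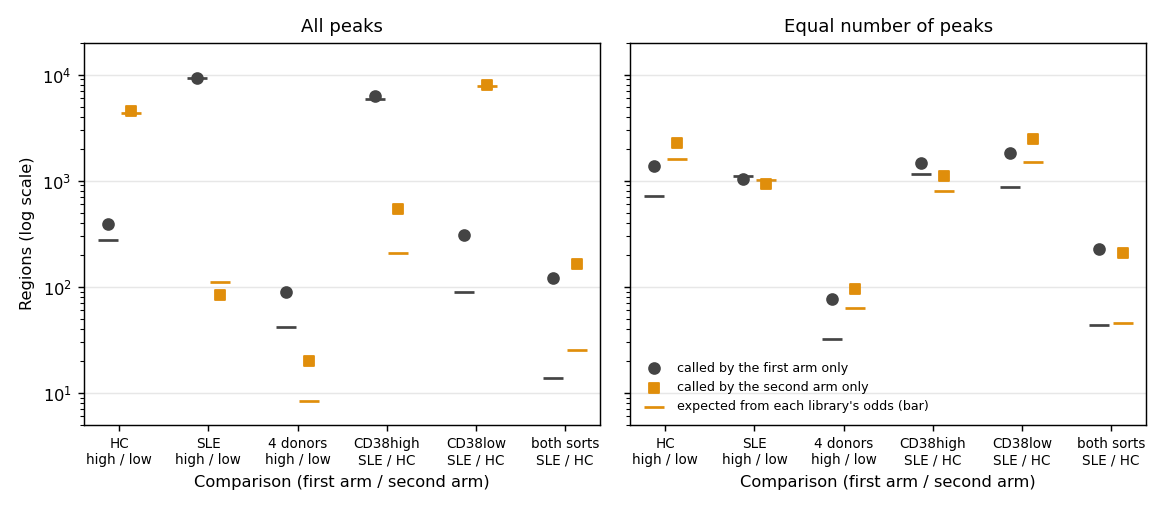
Number of regions (log scale) called in all libraries of an arm and none of the other for each of the 6 comparisons, with all peaks (left) and equal peak numbers (right), circles for the first arm, squares for the second, and bars for the number expected from each library's odds. With all peaks SLE donors show 9230 regions for CD38high and 84 for CD38low, and at equal peak numbers 1039 and 936.

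Relative to independent lists, regions that parted the sorts in HC donors parted them in SLE donors more in the same than in opposite directions. This excess was smaller without some single libraries. The HC and SLE lists come from different donors and share no library. Regions shared by both disease groups are, by definition, those counted above over the 4 donors. Independent lists were taken from all regions, 36345 at equal peak numbers, of which the 12769 called by all 8 libraries can enter neither list. Ratios above 1 are therefore partly built in. Among equal numbers of peaks, 77 regions were open in CD38high alone in both disease groups, against 39.5 for independent lists, a ratio of 1.95 (95% interval 1.54 to 2.44). In CD38low alone 96 were shared, against 58.3, a ratio of 1.65 (1.33 to 2.01). Overlaps in opposite directions lay below those of independent lists, with 17 regions open in CD38high of HC and CD38low of SLE (ratio 0.478, 0.278 to 0.765) and 27 the other way (0.417, 0.275 to 0.607). With all peaks the ratios were 1.84 for CD38high, 3.93 for CD38low and 0.676 for regions of CD38low in HC and CD38high in SLE. The CD38high ratio with all peaks was 1.08 without SLE donor 1 CD38low, and 1.23 where peaks had to cover at least 50% of a region. The CD38low ratio was 1.22 without HC donor 2 CD38high and 2.28 to 2.30 without HC donor 1 CD38low, SLE donor 1 CD38high or SLE donor 2 CD38high. Of the ratios at equal peak numbers, that of CD38low was 0.977, below independent lists, without HC donor 2 CD38high and 1.31 without SLE donor 1 CD38high, and that of CD38high was 1.22 without SLE donor 1 CD38high. Over both directions at equal peak numbers, the ratio for the same direction was 4.03 times that for opposite directions, but 1.19 times without HC donor 2 CD38high and 1.11 times without SLE donor 1 CD38high, and 2.47 times without HC donor 1 CD38low. Without any of the other 5 libraries it was 3.14 to 4.58 times.

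**Figure D4:**
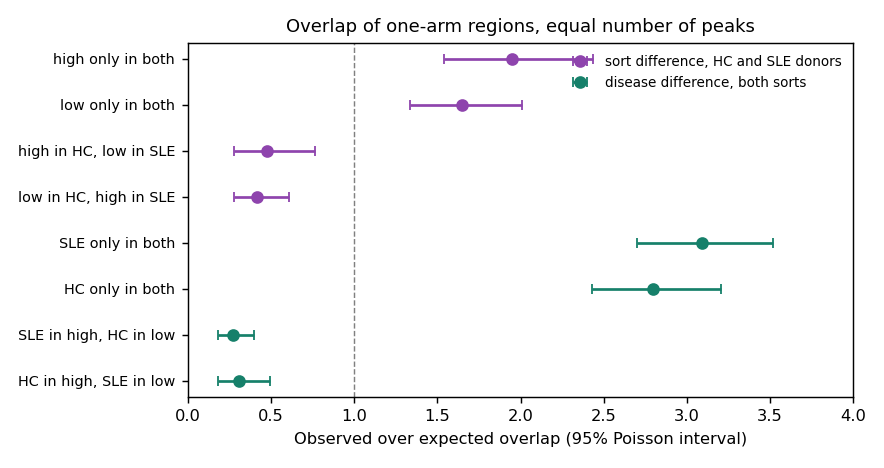
Ratio of observed to expected overlap (points, with exact 95% Poisson intervals) of regions called in a single arm at equal peak numbers, for the sort difference in HC and in SLE donors (purple) and the disease difference in CD38high and in CD38low cells (green). Overlaps in the same direction lie above 1, from 1.65 to 3.09, and those in opposite directions below 1, from 0.272 to 0.478. Ratios above 1 are partly built in, as regions called by every library can enter no list.

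Bins of 100 kb gave almost no calls between the sorts. limma found 0 of 10545 bins past an adjusted p of 0.05 for CD38high against CD38low in HC donors, in SLE donors and over the 4 donors, with 542, 688 and 576 bins at an unadjusted p under 0.05. The smallest adjusted p values were 0.863, 0.684 and 0.788. The sort difference was also compared between SLE and HC donors, and limma again found 0 bins, with 677 at an unadjusted p under 0.05 and a smallest adjusted p of 0.627. These 4 comparisons gave 0 bins at equal peak numbers too, with 838, 469, 812 and 487 at an unadjusted p under 0.05. Those fits ignore the pairing of the sorts within donors. With the donor as a block, 923, 1206, 918 and 1285 bins had an unadjusted p under 0.05 with all peaks. At equal peak numbers there were 1120, 705, 1070 and 799. Past an adjusted p of 0.05 the block again gave 0 bins in each of these comparisons. Without HC donor 1 CD38high, also at equal peak numbers, 1 bin passed for CD38high against CD38low over the donors, on chromosome 17 at 65900001 to 66000000 (limma adjusted p = 0.0424). A limma fit of 2 arms to equal peak numbers also gave 1 bin, on chromosome 5 at 58800001 to 58900000, with a mean of 434 bp in CD38high and no cover in CD38low (adjusted p = 0.0487, against 0.0833 with 4 group means).

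The second question of the design is how SLE cells differ from HC cells of the same sort. SLE libraries held 57112 ± 27751 autosomal peaks and HC libraries 62624 ± 16867 (SD, n = 4 each from 2 donors, exact permutation p = 0.743). Covered length was 9.52 ± 5.27 Mb and 8.20 ± 2.99 Mb (SD, n = 4 each, exact permutation p = 0.714). Both differences turned direction without single libraries. SLE minus HC was 4124 peaks without SLE donor 2 CD38low, and -1.12 Mb without SLE donor 2 CD38high or -0.039 Mb without HC donor 1 CD38high. Median peak width was 133 ± 9.02 bp in SLE and 99.0 ± 31.8 bp in HC (SD, n = 4 each, exact permutation p = 0.114). Chromosome 19, rich in genes, held 5.56% ± 0.582 of the peaks in SLE and 4.47% ± 0.662 in HC. Chromosome 4 held 3.78% ± 0.194 and 4.88% ± 1.17 (SD for both, n = 4 each from 2 donors). Exact permutation over libraries gave p = 0.0571 for both, and 0.285 after adjustment over 10 tests. Over donors, 2 against 2, an exact p cannot go below 0.33. These 2 chromosomes were not in the plan. Within donors the larger library had the lower chromosome 19 share, except in SLE donor 1. In SLE donor 2 the share was 6.21% with 28206 peaks and 4.80% with 94599.

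Over both sorts 122 regions were open in all 4 SLE libraries and no HC library, and 163 in all 4 HC libraries and no SLE library. These were 8.80 and 6.43 times the expected 13.9 and 25.3. Single libraries turned the direction, with 759 and 168 regions without SLE donor 2 CD38low and 323 and 266 without HC donor 2 CD38low. With equal peak numbers the counts were 227 and 208, 5.17 and 4.58 times those expected. The 5 longest open in SLE alone lie on chromosome 13 at 113180353 to 113181291 (939 bp), chromosome 10 at 134241336 to 134242018 (683 bp), chromosome 20 at 56803329 to 56803913 (585 bp), chromosome 19 at 3284961 to 3285525 (565 bp) and chromosome 14 at 106995663 to 106996217 (555 bp). The regions on chromosomes 20 and 14 met the rule at equal peak numbers as well. The 5 longest open in HC alone lie on chromosome 1 at 142537470 to 142537830 (361 bp), chromosome 3 at 31857219 to 31857542 (324 bp), chromosome 13 at 95828906 to 95829218 (313 bp), chromosome 10 at 15227433 to 15227708 (276 bp) and chromosome 3 at 107694786 to 107695055 (270 bp). None of these 5 met the rule at equal peak numbers. As repeats were not filtered out, mapping artifacts among the named regions are not excluded. With 2 donors per disease group, a difference between donors cannot be set apart from a difference between groups by these counts.

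Within CD38high cells 6237 regions were open in SLE alone and 537 in HC alone, and within CD38low cells 306 and 8025. In each sort the larger count lay in the disease group with more peaks on average. The expected counts were 5909 and 209 in CD38high and 89.4 and 7808 in CD38low. Here too the fitted odds fix the difference between the directions, so these values say nothing about its source. Equal peak numbers gave 1474 and 1103 in CD38high and 1813 and 2452 in CD38low. The shares open in SLE alone were then 57.2% and 42.5% instead of 92.1% and 3.67%. Relative to expectation at equal peak numbers the real split stood at 1.31 in CD38high and 1.80 in CD38low, above the other splits of the same 4 libraries (at most 0.942 and 0.681). With all peaks the real split stood at 1.11 and 1.05 and the other splits at most at 0.994 and 0.984. As for the sorts, the ratios of these splits are tied to a common total and are not independent. Of the named regions, the longest open in CD38high SLE cells alone is the 965 bp region on chromosome 12. The longest in CD38low SLE cells is the 939 bp region on chromosome 13. For HC alone the longest in CD38high lies on chromosome 10 at 38818185 to 38818639 (455 bp), and another of the 5 lies close by at 38817465 to 38817824 (360 bp). In CD38low it lies on chromosome 1 at 116518571 to 116519368 (798 bp). Mapping artifacts are not excluded for these regions either. The region on chromosome 6 at 20023848 to 20024466 (619 bp), open in CD38low HC cells alone, had high scores, from 165 to 1237, and met the rule at equal peak numbers.

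Relative to independent lists, regions that parted SLE from HC in CD38high cells did so in CD38low more in the same than in opposite directions. Regions shared by both sorts are, by definition, those counted above over both sorts, so their overlap is no separate evidence. Here too ratios above 1 are partly built in, as regions called by all 8 libraries can enter neither list. Among equal numbers of peaks, 227 regions were open in SLE alone in both sorts, against 73.5 for independent lists, a ratio of 3.09 (95% interval 2.70 to 3.52). For HC alone the count was 208 against 74.4, a ratio of 2.80 (2.43 to 3.20). Overlaps in opposite directions had ratios of 0.272 and 0.309. They hold the same 27 and 17 regions as the opposite overlaps of the sort lists. With all peaks the ratios were 4.74 for SLE alone, 2.81 for HC alone and 0.560 for SLE alone in CD38high and HC alone in CD38low. Without single libraries they were as low as 1.84 for SLE alone, without HC donor 2 CD38high, and 1.51 for HC alone, without HC donor 1 CD38low. Over both directions the ratio for the same direction was 10.3 times that for opposite directions at equal peak numbers and 6.09 times with all peaks. At equal peak numbers it was at least 1.94 times without any 1 library, the lowest being without SLE donor 1 CD38high. Without that library the ratios were 1.90 for SLE alone and 1.49 for HC alone, and without HC donor 2 CD38high that for SLE alone was also 1.90. Both lists rest on the same 4 donors, so part of the excess can come from donor differences that both sorts carry.

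In 100 kb bins with all peaks, limma found 0 of 10545 bins past an adjusted p of 0.05 for SLE against HC in CD38high, in CD38low and over both sorts, with 842, 737 and 921 bins at an unadjusted p under 0.05. The smallest adjusted p values were 0.488, 0.455 and 0.236. With equal peak numbers the counts were 0 in CD38high (700 unadjusted), 20 in CD38low (10 higher in SLE and 10 higher in HC) and 25 over both sorts (14 higher in SLE and 11 higher in HC). With the donor as a block the last count was 3. That for CD38low was 21, but each donor has a single CD38low library, so the block cannot take account of the donor there. The count of 25 fell to 0 without HC donor 2 CD38low and stood at 1, 2, 2, 3, 5 and 11 without HC donor 1 CD38low, HC donor 2 CD38high, SLE donor 1 CD38low, HC donor 1 CD38high, SLE donor 2 CD38low and SLE donor 2 CD38high. It was 47 without SLE donor 1 CD38high, and the count in CD38high was then 6 instead of 0. The count of 20 in CD38low fell to 0 without any one of the 4 CD38low libraries and to 12, 9, 6 and 6 without HC donor 1, HC donor 2, SLE donor 1 or SLE donor 2 CD38high.

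The 10 bins of hg19 with the largest difference in each direction over both sorts at equal peak numbers were named. Higher in SLE, by size of the difference, were those starting on chromosome 5 at 900001, chromosome 20 at 61600001, chromosome 8 at 141800001, chromosome 21 at 32700001, chromosome 17 at 79700001, chromosome 3 at 111400001, chromosome 21 at 47000001, chromosome 1 at 235800001, chromosome 8 at 1700001 and chromosome 19 at 5800001. Higher in HC were those starting on chromosome 8 at 59100001, chromosome 8 at 37100001, chromosome 13 at 33300001, chromosome 5 at 109100001, chromosome 2 at 88500001, chromosome 5 at 142200001, chromosome 10 at 22000001, chromosome 13 at 49300001, chromosome 3 at 153300001 and chromosome 8 at 129500001. With the donor as a block, 3 of the 25 bins passed. The first, on chromosome 8 at 59100001 to 59200000, was covered over 283 bp to 807 bp in HC and not covered in any SLE library among equal numbers of peaks (limma adjusted p = 0.00422, and 0.00826 with the block). With all peaks its mean was 594 bp in HC and 392 bp in SLE, a log2 difference of -1.01 (limma adjusted p = 0.329). The second, on chromosome 5 at 900001 to 1000000, was covered over 333 bp to 931 bp in SLE and not covered in HC (adjusted p = 0.0184, and 0.031 with the block). Its means with all peaks were 1053 bp in SLE and 357 bp in HC, a log2 difference of 1.30 (adjusted p = 0.254). The third, on chromosome 5 at 109100001 to 109200000, had means of 592 bp in HC and 201 bp in SLE (log2 -1.73, SE 0.15, adjusted p = 0.0184, and 0.031 with the block), and a log2 difference of -1.07 with all peaks (adjusted p = 0.356). The other 22 had blocked adjusted p values from 0.0506 to 0.116. With all peaks 24 of the 25 bins kept their direction and 0 passed, and their log2 differences ran from -0.07 to 1.60 for the bins higher in SLE and from -1.43 to -0.51 for those higher in HC (adjusted p from 0.236 to 0.959).

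Most of the 20 bins that passed in CD38low cells at equal peak numbers had 0 bp in both libraries of a group. All 10 bins higher in HC had 0 bp in both SLE CD38low libraries. This leaves little spread within that group, and with all peaks both groups had cover in these bins. Of the 20 bins, 11 were among the 25. The others start on chromosome 13 at 21900001, chromosome 14 at 39800001, chromosome 1 at 232500001, chromosome 16 at 12600001 and chromosome 14 at 72100001, higher in HC, and on chromosome 4 at 2000001, chromosome 6 at 126600001, chromosome 19 at 34900001 and chromosome 6 at 151100001, higher in SLE. With all peaks 20 of 20 kept their direction on the normalized log2 scale and 0 passed (limma adjusted p from 0.455 to 0.849). Plain mean cover was nonetheless higher in HC on chromosome 8 at 1700001 (574.5 bp, and 511.5 bp in SLE). The same held on chromosome 4 at 2000001 (447 and 370.5 bp) and chromosome 19 at 34900001 (413 and 385 bp).

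**Figure D5:**
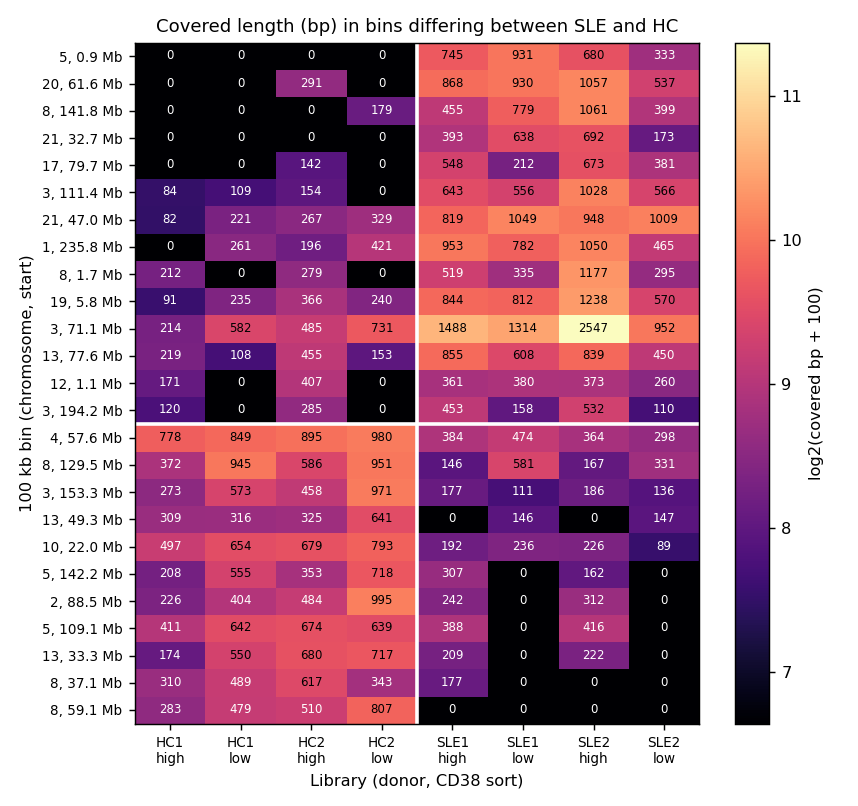
Covered length in bp (numbers in the cells, colour on a log2 scale) in each of the 8 libraries for the 25 bins of 100 kb that passed limma's threshold for SLE against HC over both sorts at equal peak numbers, the 14 higher in SLE above the white line and the 11 higher in HC below it. The bin at 59.1 Mb on chromosome 8 shows 0 bp in the 4 SLE libraries and 283 bp to 807 bp in the 4 HC libraries.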

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

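The tests of weak peaks of no other library, of regions of middling strength, of disease or other donor differences, of equal peak widths, of splits without a donor, of all splits counted by regions, and of the splits counted by bins at equal peak numbers were chosen only after the result was seen.

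The 2 disease groups moved in opposite directions between the sorts. The CD38high library held 0.501 and 0.895 times the autosomal peaks of the CD38low library in HC donors 1 and 2, and 1.17 and 3.35 times in SLE donors 1 and 2. Covered length had ratios of 0.497, 0.795, 1.14 and 3.89 in the same order. Every HC donor moved one way and every SLE donor the other. A test of the difference over 4 donors gives an exact permutation p of 0.333, the smallest that 2 donors against 2 allow, so the difference stays undecided.

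For this pattern a difference in depth or detection between the libraries of a donor is a candidate explanation. The smaller library of each donor called at least 93.8% of the strongest 10% of the larger one's peaks, but libraries of the other donors called on average at least 95.4% of them, so this test decides nothing and depth stays open. Peaks that no other library overlaps made up at most 20.5% of the gap in HC donor 2 and SLE donor 1, which argues against such peaks as the source of the gap there. In HC donor 1 and SLE donor 2 they made up 43.9% and 42.0%, too little to explain most of the gap and too much to set them aside. An effect of disease on the sort difference cannot be told apart from depth with these 4 donors (exact permutation p = 0.333).

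Regions that part the sorts in the same direction in HC and SLE donors form the second pattern. If regions of middling strength entered both lists by chance, opposite directions would overlap as often as like ones, and the ratio for the same direction was 4.03 times that for opposite ones at equal peak numbers. Without HC donor 2 CD38high it was 1.19 times and without SLE donor 1 CD38high 1.11 times, so that this explanation stays open. Among the 8 splits of the libraries that part the pair of each donor, 1, the real one, gave as many regions (173, against at most 115), and 8 splits are too few for a share under 0.05. A difference between CD38high and CD38low cells common to HC and SLE donors may also explain the pattern, and these 2 explanations cannot be told apart while 2 libraries decide the value.

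The third pattern is the excess of regions parting SLE from HC at equal peak numbers. HC donor 1, with narrow peaks, stays open as its source: the real split of the donors gave at least 4.77 times the expected regions with every peak set to the same width, beyond the intervals of the other splits, but without this donor SLE donor 1 against the rest gave 2.04 times and SLE against HC 1.55, while the lower overlap ratio of 2.25 then rests on 1 HC donor in both sorts and decides nothing. Without SLE donor 1 or SLE donor 2 the split of SLE against HC was the highest (1.91 and 2.35, next 1.57 and 1.32). Both next values are those of HC donor 1 against the rest, which goes against this donor. Without HC donor 2 that split was also the highest (1.89, next 1.79), with overlapping intervals. It is then the same as HC donor 1 against the rest, so this omission decides nothing. The omissions thus disagree, and their intervals cover counting error only. Regions open in SLE alone lay on the gene-rich chromosomes 16, 17, 19, 20 and 22 in 31.3% of cases. Those open in HC alone did in 8.17%, against 21.3% of all regions. The lower overlap ratio was still 2.68 within 10 classes of region density and 2.43 within windows of 1 Mb. Such ratios are partly built in, as regions called by every library can enter no list. They therefore go only weakly against these trends as the whole source. What also stays open is the GC content of single regions, which was not tested, disease, other differences between the donors, and preparation, since sample numbers in the peak names run from 1 to 4 in HC and from 9 to 12 in SLE: the real split of the 4 donors gave 435 regions and the other 2 at most 132, which 3 splits cannot bring to a share under 0.05, so these cannot be told apart.

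Counts were also set beside those of other splits of the 8 libraries. With all peaks, 14 of the 35 splits gave as many regions as CD38high against CD38low (109) and 8 of 35 as many as SLE against HC (285), so chance cannot be excluded for either count. These counts follow peak numbers: relative to the number expected from the libraries' odds, 1 of 35 splits was as high as the disease (7.27, next 2.16) and 2 of 35 as high as the sort (2.16), and at equal peak numbers 1 of 35 gave as many regions as the disease (435, next 304) and 5 of 35 as many as the sort (173). The 2 libraries of a donor are not independent. With all peaks, 4 of the 8 splits that part each donor's pair gave as many regions as the sort (109, against at most 378), and 1 of the 3 that keep donors whole, the real one, as many as the disease (285, against at most 184). Relative to expectation only the real split of these 8 was as high as the sort (2.16, next 0.908), and only the real one of the 3 as high as the disease (7.27, the others being below expectation), but 8 and 3 splits are too few for a share under 0.05. The highest of all 35 splits with all peaks gave 1752. It set the 4 libraries with the least covered length against the 4 with the most. This was 1.07 times the 1630 expected from the libraries' odds, so it shows little beyond those odds. In limma fits of 2 arms to 100 kb bins with all peaks, at an unadjusted p under 0.05, 19 of 35 splits gave as many as the sort (473) and 6 of 35 as many as the disease (870), again with chance not excluded, and the same split by covered length gave 1860. Of the 8 splits that part each pair 3 gave as many bins as the sort (473, against at most 758), and of the 3 that keep donors whole 1, the real one, as many as the disease (870, against at most 616). With equal peak numbers 1 of the 3 splits that keep the donors whole, the real one, gave as many bins past an adjusted p of 0.05 in a limma fit of 2 arms (19, against at most 1) or as many regions (435, against at most 132), and 3 splits are too few for a share under 0.05.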

How the results depend on the processing

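The alternatives that take 50 kb or 500 kb bins, other scalings, pseudocounts or filters of bins, that require peaks to cover 50% of a region, that leave out both libraries of HC donor 1, that leave out a library at equal peak numbers, and all those of the disease overlap and the bins were chosen after seeing the data. Among alternatives other than leaving out a library, the best-scoring 50% of peaks gave covered length differences of 1.30 Mb between the sorts and 0.688 Mb between SLE and HC (exact permutation p = 0.543 and 0.857). Peak numbers with that 50%, and sign flips, could not have come out otherwise. Of the counts of regions, 46 of 82 such values stayed within 1.5 times the main count. Counts with regions of a single library kept could not move. Nor could those over the 4 donors or both sorts with at least 3 libraries. For the overlaps, 3 of 14 ratios of the sort and 3 of 14 of the disease stayed in the interval of the main value. Bins stayed at 0 in 73 of 77 counts, a floor that cannot show stability. At an unadjusted p under 0.05 for the sorts over the 4 donors were 576 of 10545 bins with the filter on covered length. Without it there were 1553 of 25135, so that the rise goes with the larger number of bins tested. Depth, unknown here, limits every count of regions, and the cause of the changes below was not tested except where fewer peaks or libraries enter by construction. The overlap rule fixed in advance, which also counts a peak lying at least 50% inside a region, changes nothing, since every peak lies inside its merged region. The settings fixed in advance for accessible length per gene, gene lists, called regions of gene lists, genomic location and sequence motifs were not run.

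With the best-scoring 50% of peaks, SLE donors had 4894 regions in CD38high alone and 43 in CD38low alone, the 4 donors 10 in CD38low alone, and SLE alone held 2676 in CD38high, 126 in CD38low and 63 over both sorts. The sort overlap ratios were 2.58 (CD38high) and 2.07 (CD38low), and the disease overlap ratios 7.67 (SLE) and 2.05 (HC). With equal peak numbers, CD38high and CD38low alone counted 1381 and 2265 in HC, 1039 and 936 in SLE, and 96 in CD38low over the 4 donors. SLE and HC alone counted 1474 and 1103 in CD38high, 1813 and 2452 in CD38low, and 227 in SLE over both sorts. The overlap ratios were 1.65 (CD38low) and 3.09 (SLE), and 20 (CD38low) and 25 (both sorts) bins passed for SLE against HC, against 0 with all peaks. With peaks covering 50% of a region, 49 regions in CD38high over the 4 donors and 84 in HC over both sorts were counted, with ratios of 1.23 (CD38high), 2.09 (CD38low), 3.16 (SLE) and 2.27 (HC). With regions of a single library kept these ratios were 4.03, 8.60, 10.4 and 6.14, since the list of regions grows. With at least 3 libraries, 2.62 (CD38high) and 5.76 (SLE).

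Without both libraries of HC donor 1, which leaves 1 library in each HC arm, CD38high and CD38low alone counted 6072 and 11999 in HC and 1437 and 33 over the 3 donors left, and HC alone 2336 in CD38high, 18084 in CD38low and 1794 over both sorts. The ratios were 2.32 (CD38low) and 3.93 (SLE). Equal peak numbers without this donor gave 4329 regions for CD38high alone in HC, 304 and 224 for CD38high and CD38low over donors, and for SLE and HC alone 1866 and 1856 in CD38high, 2891 and 3112 in CD38low, and 359 and 809 over both sorts, with ratios of 2.28, 1.90, 2.25 and 4.74.

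With the replicate block, the donor, no region passed an exact sign test (0 in each direction), as 4 donors cannot go below 0.125. Sign flips within donors gave exact p values of 0.75 for peak number and 0.875 for covered length. With the donor as a block and equal peak numbers 21 (CD38low) and 3 (both sorts) bins passed for SLE against HC. The block changed no other call. A fit of 2 arms at equal peak numbers passed 1 bin between the sorts and 19 between SLE and HC.

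Leaving out each library in turn, the difference between CD38high and CD38low ran from -3360 to 15175 peaks and from -0.585 to 3.64 Mb, and SLE minus HC from -18007 to 4124 peaks and from -1.12 to 3.05 Mb. It turned to -3360 peaks and -0.585 Mb between the sorts without SLE donor 2 CD38high and to -2337 peaks without SLE donor 2 CD38low. Between the disease groups it turned to 4124 peaks without the latter, -1.12 Mb without the former and -0.039 Mb without HC donor 1 CD38high. CD38high and CD38low alone ran from 488 to 5186 and 4879 to 19727 in HC, 9448 to 23452 and 185 to 1463 in SLE, and 93 to 1251 and 22 to 263 over the 4 donors. SLE and HC alone ran from 6400 to 24224 and 1111 to 2671 in CD38high, 421 to 3062 and 9139 to 20243 in CD38low, and 123 to 759 and 168 to 695 over both sorts. The larger direction turned without HC donor 1 CD38high in HC, without SLE donor 2 CD38low over the 4 donors, and without SLE donor 2 CD38low or HC donor 2 CD38low between SLE and HC over both sorts. An arm with fewer libraries admits more regions by construction. Ratios ran from 1.08 to 2.04 (CD38high), 1.22 to 4.43 (CD38low), 1.84 to 4.61 (SLE) and 1.51 to 3.58 (HC). At equal peak numbers, the ratio of same to opposite directions ran from 1.11 to 4.58 for the sorts and from 1.94 to 10.3 for disease. With all peaks, bins for SLE against HC over both sorts ran from 0 to 1, the 1 without HC donor 1 CD38high, and at equal peak numbers from 0 to 47. In bins, a library left alone in its group is assumed to vary like the others.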

Other observations

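The position of these regions differed by direction, a description chosen after the data were seen. Of the 227 regions open in SLE alone at equal peak numbers 25 lay on chromosome 19, and 2 of the 208 open in HC alone, against 5.77% of all 36345 regions. Of the 77 regions open in CD38high alone over the 4 donors 6.49% lay there, and of the 96 open in CD38low alone 1.04%. On the gene-poor chromosomes 4, 13 and 18 lay 9 of the regions open in SLE alone and 25 of those in HC alone, against 7.46% of all, and 5 of those in CD38high alone (6.49%) and 4 of those in CD38low alone (4.17%). Regions open in SLE alone had a median width of 260 bp and those in HC alone 184 bp, and for CD38high and CD38low alone the medians were 268 bp and 189 bp. The width of a region is that of the merged peaks of the libraries calling it. With all peaks, median peak width was 133 bp in SLE and 99 bp in HC libraries, but 115 bp in CD38high and 117 bp in CD38low. How far peak width accounts for region width was not tested. Regions are not replicates, and these shares were not tested.

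Outside the autosomes, peaks on unplaced contigs numbered 473 and 492 in the libraries of HC donor 1 and 86 to 246 in the other 6, and mitochondrial peaks numbered between 18 and 33 per library. These peaks entered no comparison.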
